A study of Mus musculus with 6 samples.

How the data were processed

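RNA from sorted DN3 thymocytes of 3 wild-type and 3 miR-185 Tg samples was hybridised to Illumina MouseWG-6 v2.0 BeadChip arrays, 6 arrays on 1 chip, so slide and group are not confounded. Groups and replicate numbers come from the sample titles. Per the labels' protocols, RNA was extracted with a column kit, treated with DNase, checked on a Bioanalyzer and turned into biotinylated cRNA. Per the file headers, the deposited probe table was written by GenomeStudio 1.9.0 with no normalization. Its values are the mean bead intensity of each probe, deposited without a log, with a detection score from 0 to 1, the number of beads and the SD between beads. The detection score, per the file headers a GenomeStudio column, is 1 for the brightest probes and was read as 1 minus the detection p-value. Whether the background had been subtracted is not given in the sources used here, and the lowest intensity of each array lay between 83.9 and 91.1, well above 0. A second deposited table holds the intensity averaged over the probes of a gene. The authors' series values are the log2 of that table (largest difference 6.3e-07 over 34749 values per array), with column medians of 6.65 to 6.78, so they are not normalized between arrays. Their log base and their lack of centring and scaling follow from that match, and they are intensities, not ratios, so no direction is involved.

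The probe intensities were corrected with normexp fitted from the detection p-values (offset 16) and quantile normalized, as in neqc of limma 3.58.1 in R 4.3.3. Of 45281 probes, 18597 with a detection p under 0.05 on at least 3 of the 6 arrays, whatever their group, were kept. A gene with several kept probes was represented by the probe with the highest mean over all arrays. Gene names in the table are those of the array's design. Of 30774 distinct names, 15991 matched a current RefSeq symbol and 5826 a unique synonym in the gene table of assembly GRCm38.p6, and 8957 were kept as they stand. That table was used for names and for which genes neighbour each other, and positions are not given, since the genome build behind the array tables is not given in the sources used here.

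The 12426 genes were tested with lmFit and eBayes with a trend, and called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are Tg over wild type on the normalised log2 scale, which understates the change of dim genes. For a probe detected on no array of a group, a fold is given as at least a value, from the mean of the bright group against the mean, over the arrays of the dim group, of the higher of the probe's own signal and the lowest signal among detected probes. Before the data were examined, 25 gene lists were fixed, of which the 23 with at least 3 measured members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, all two-sided and adjusted over the lists. Also fixed then were the named genes: all measured study targets and Mir185 host and neighbouring genes; the 12 genes with the largest rise and the 12 with the largest fall among called genes whose groups do not overlap, without predicted genes and clones; and up to 4 members of each list with the smallest unadjusted p. Other genes named, such as the further members called over their list alone and the remaining technical and MHC genes, were chosen after their values were seen. The values of some genes that the rule names are not reported here.

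The gene and list tests were tested on simulated data with the 12426 genes, 3 arrays against 3 and 200 changed genes in 10 draws. They found 32.6% of genes changed by 1 and 81.2% of genes changed by 2 on the log2 scale, 100% of them with the right sign, with 4.5 false calls per draw on average. A list shifted by 0.5 was called in 10 of 10 draws, with 0.1 other lists called on average. The simulated genes varied independently of each other, while estimated correlations within the real lists reached 0.46. The draws therefore do not measure how often a list is called falsely when its members vary together. The simulated arrays were also independent and equally variable, while the real wild type 2 and 3 lay close together and Tg 2 stood apart. The false calls and the shares found may therefore not hold for the real arrays. Alternatives covered the background correction, offset, normalization, the authors' series values, the filter, the variance model, array weights, a replicate block, each array left out, the probe rule, thresholds and the test. The average of wild type 2 and 3, the loss of both, and covariates for Hbb-b1 and Ddx3y were added after seeing the data. The planned test of genes with miR-185 seed sites was not run, since transcript and probe sequences were not used here, so direct and indirect effects of miR-185 were not analysed here.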

Results

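Gene expression was measured in DN3 thymocytes, the immature thymic T cells that lack CD4 and CD8 and undergo selection for a rearranged T cell receptor beta chain. The cells were sorted from thymus as CD44 negative and CD25 positive cells, without CD4, CD8, B220, NK1.1, gamma-delta T cell receptor, CD11b or CD11c. There were 3 samples from wild-type C57BL/6 mice and 3 from mice carrying a miR-185 transgene (miR-185 Tg), each on 1 array. Each array had a median of 41 to 42 beads per probe, and between 17879 and 18913 of 45281 probes were detected, or 39.5% to 41.8%. The number of arrays limits the precision. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

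The arrays did not stand at equal distances from each other. The first principal component held 44.0% of the variance and set Tg 2 apart from the other 5 arrays, and the second held 34.7%. Wild type 2 and wild type 3 correlated across probes at r = 0.996 (genes are not independent replicates). Their mean squared difference over 3109 bright probes was 3.03 times the bead noise, against at least 35.2 times for any other pair. Their median squared difference was 1.05, against 0.455 from bead noise alone, and all 10 kept Hbb-b1 probes were higher in wild type 3, by 0.55 to 1.02 on the log2 scale. They differed by more than the bead noise and were kept as 2 samples. Separate preparations from one animal or pool would also differ by more than bead noise, so this is not excluded, and with the 2 arrays averaged as 1 sample 36 genes changed in place of 526. Red blood cell and sex-linked transcripts also varied between arrays. Hbb-b1, a beta globin gene, had log2 intensities of 8.0, 12.40 and 13.12 in wild type 1, 2 and 3 and of 9.58, 10.21 and 9.40 in Tg 1, 2 and 3. S100a8, an abundant neutrophil transcript, was detected on 3 wild-type arrays, with log2 intensities of 5.44, 5.80 and 7.96 in wild type 1, 2 and 3, and on 0 Tg arrays, and did not pass (adjusted p = 0.081, limma). The Y-linked gene Ddx3y had a log2 intensity of 6.06 in Tg 2 and of 9.06 to 10.49 on the other arrays. Xist, the RNA of the inactive X chromosome of female cells, was also lowest in Tg 2, at 9.02, and had values of 12.30 in Tg 3 and 9.23 to 10.41 on the other 4 arrays. Ddx3y and Xist were each detected on all 6 arrays, with both at their lowest in Tg 2. The Y-linked genes Eif2s3y and Kdm5d were also lowest in Tg 2, at 4.56 and 4.30. Both lay below the lowest detected signal of that array, 4.69, so they were not detected there. Transcripts of both sexes were thus present, but those of Y-linked genes were scarce in Tg 2. The labels do not say whether a sample came from a single mouse or a pool.

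**Figure D1:**
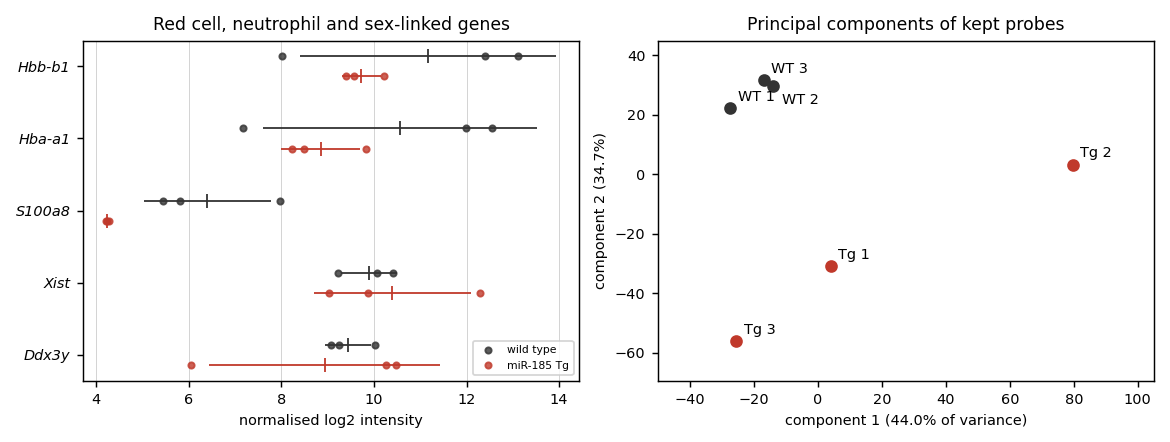
Left, normalised log2 intensity of Hbb-b1, Hba-a1, S100a8, Xist and Ddx3y on each of the 6 arrays (points), with the mean and SD of each group of 3 (bars). Right, the first 2 principal components of the kept probes, with the percent of variance on each axis. Hbb-b1 lies at 12.40 and 13.12 in wild type 2 and 3, and Tg 2 lies apart on component 1.

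The study set out to find genes that respond to miR-185 in DN3 cells. Compared with wild type, miR-185 Tg cells had higher levels of the dystrophin-complex gene Dtna, of MHC class I genes of the Qa-2 region, of the surface protein Ly6a (Sca-1) and of interferon-induced genes such as Oasl2. They had lower levels of Mzb1, which encodes an endoplasmic reticulum protein, of the calcium/calmodulin-dependent kinase gene Camk4, of the homeobox gene Hoxa7 and of the gap junction gene Gja1. Of 12426 genes tested, 526 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 317 of them higher and 209 lower in Tg cells. Of these, 384 changed at least 2-fold and 52 at least 4-fold, of which 38 were higher and 14 lower. In all 526 genes the 3 Tg values lay on one side of the 3 wild-type values. Genes called by a test of group means are selected for such separation. It also held in 28.2% of all tested genes. Chance gives 10% if all arrays are independent and equally variable, but wild type 2 and wild type 3 lay close together. The 10% may therefore be too low, and the 28.2% cannot be read as a measure of the group difference. The count of changed genes depended on single arrays. It was 1 without wild type 1, 47 without wild type 2 and 2 without wild type 3. Without Tg 1 it was 48, and without Tg 2 it was 1708. Dtna was the 1 gene called whichever array was left out.

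Dtna showed the largest rise. None of its 5 probes was detected on a wild-type array and all 5 were detected on each Tg array. Its brightest probe had a log2 intensity of 10.77 ± 0.31 in Tg cells (SD, n = 3) against 4.36 ± 0.05 in wild type (SD, n = 3), at least 68.4-fold higher, with an adjusted p of 5.9e-05 by limma. B4galnt2, a glycosyltransferase gene, was also not detected in wild-type cells and was at least 8.31-fold higher in Tg cells. H2-Q8, H2-Q6 and H2-Q7 rose by 4.09 ± 0.37, 3.94 ± 0.33 and 2.74 ± 0.31 on the log2 scale (SE). These class I genes are close copies of each other, so a probe of one can bind transcripts of another and the share of each is uncertain. Ly6a rose by 3.06 ± 0.21 from a log2 intensity of 9.42, and Oasl2, an interferon-induced gene, rose by 2.72 ± 0.28 (SE). Camk2b, a calmodulin-dependent kinase gene, rose by 2.78, the G protein-coupled receptor gene Gpr18 by 2.70, and the inflammatory caspase gene Casp4 by 2.63. Adgre5, which encodes the adhesion receptor CD97, rose by 2.56, and Dtx1, a target of Notch signals, by 2.54. The adjusted p of these 12 genes was at most 0.028.

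Among the genes with the largest falls, Cpsf4l fell by 2.73 ± 0.27 on the log2 scale (SE), Epop, whose product binds Polycomb complexes, fell by 2.63 ± 0.27, and Tpst1, a tyrosylprotein sulfotransferase gene, fell by 2.50 ± 0.29. Hoxa7 fell by 2.38 ± 0.21, from a log2 intensity of 9.77 to 7.39. Gja1, which encodes a connexin, fell by 2.26, the transcription factor gene Sox12 fell by 2.21 and the tetraspanin gene Cd81 fell by 2.13. The imprinted RNA H19 fell by 2.11 ± 0.47 (SE; adjusted p = 0.048, limma), while Pgam2, a phosphoglycerate mutase gene, and Gpr83, a G protein-coupled receptor gene, each fell by 1.98. Gpr83 was detected on 2 of the 3 Tg arrays.

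**Figure D2:**
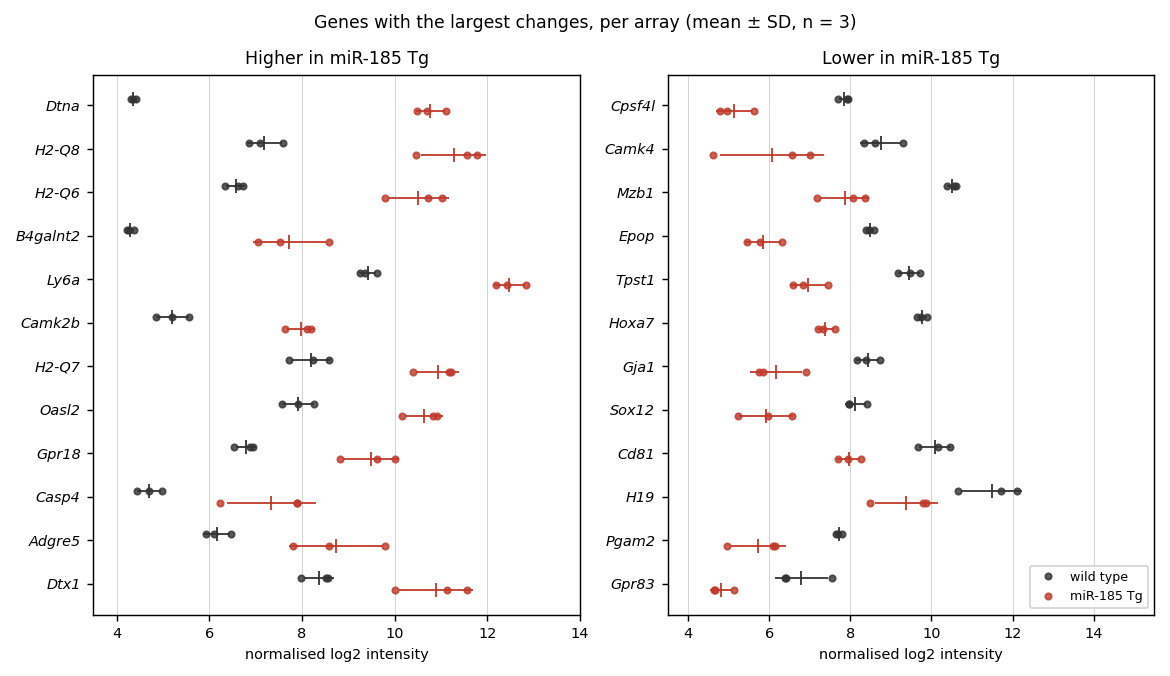
Normalised log2 intensity of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in miR-185 Tg cells, with 1 point per array and the mean and SD of each group of 3 (bars). The 3 Tg points lie apart from the 3 wild-type points for each gene, and the Dtna points lie at 4.36 on average in wild type and 10.77 in Tg.

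Mzb1, Nfatc3 and Camk4 are known as targets that this study named. They were chosen on these samples, so their direction is not independent evidence. All 3 fell in miR-185 Tg cells. Mzb1 had a log2 intensity of 10.52 ± 0.13 in wild type and 7.86 ± 0.61 in Tg cells (SD, n = 3 each). It fell by 2.65 ± 0.31 (SE; adjusted p = 0.0082, limma). Camk4 fell by 2.69 ± 0.60 (SE; adjusted p = 0.049, limma) and was detected on 2 of the 3 Tg arrays. Camk4 rests on 1 kept probe, since its other probes were detected on 2 and 0 of the 6 arrays. Its call was lost under median scaling, cyclic loess and no trend (adjusted p = 0.055, 0.060 and 0.056), and without Tg 2 its log2 fold change was -1.94 (adjusted p = 0.012). Nfatc3, a transcription factor gene of the calcineurin pathway, fell by 1.33 ± 0.23 (SE; adjusted p = 0.023, limma) at its brightest probe. A second probe was lower by a log2 difference of -1.41, while of 3 dimmer probes of Nfatc3, 2 had positive differences, 0.29 and 0.50, and 1 had a difference of -0.53. With the mean of its probes Nfatc3 did not pass, with a log2 fold change of -0.50 (adjusted p = 0.42, limma). As a list, the 3 genes were lower than the other genes (camera, adjusted p = 0.00027), with an adjusted p = 0.20 with an estimated correlation, and all 3 fell when adjusted over the list alone. An exact two-sided permutation test of 3 against 3 gave p = 0.1 for each gene, the smallest p it allows. None of the 3 (0) was called without wild type 1, wild type 2 or wild type 3, where the adjusted p of Mzb1 was 0.057, 0.051 and 0.067 in limma, and 1, Mzb1, was called without Tg 1.

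Interferon response genes were higher as a list at the preset correlation, with 18 members positive and 8 not passing in limma over all genes. Of 19 measured members of the list, 11 rose and 0 fell, and 15 rose when adjusted over the list alone. Oasl2 rose by 2.72 ± 0.28 and the transcription factor gene Irf7 by 2.24 ± 0.28 on the log2 scale (SE). Usp18, which encodes a protease that removes ISG15, rose by 1.89 ± 0.21 (SE). The GTPase gene Igtp was 3.73-fold higher and the immunoproteasome gene Psmb9 2.82-fold higher. The median log2 fold change of the list was 1.28 (camera, adjusted p = 5.1e-12), with an adjusted p = 0.20 with an estimated correlation. Bst2, another interferon-induced gene, had a log2 fold change of -0.11 ± 0.42 (SE; adjusted p = 0.93, limma).

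Cell cycle genes were lower as a list, with a median log2 fold change of -0.53 over 29 measured members, 28 of them negative (camera, adjusted p = 1.7e-07; adjusted p = 0.20 with an estimated correlation). Of these, 2 fell over all genes tested and 8 fell when adjusted over the list alone. Mcm5, part of the replicative helicase, fell by 1.20 ± 0.12 on the log2 scale and Cdc6, a replication licensing factor gene, fell by 0.90 ± 0.19 (SE). The cyclin gene Ccnb1 had a log2 fold change of -0.88 ± 0.20 and the spindle checkpoint gene Bub1b of -0.65 ± 0.15 (SE; adjusted p = 0.050 and 0.051, limma). Glycolysis genes were also lower as a list, with a median of -0.32 over 17 members (camera, adjusted p = 0.0029; adjusted p = 0.42 with an estimated correlation). Ldha, which encodes a lactate dehydrogenase subunit, fell by 0.60 ± 0.11 and Tpi1, triosephosphate isomerase, fell by 0.83 ± 0.15 (SE), while 15 members did not pass the test; the same 2 passed when adjusted over the list alone. Without Tg 2 the glycolysis median was -0.56. Cholesterol synthesis genes had a median of -0.26 over 22 members (camera, adjusted p = 0.043; adjusted p = 0.42 with an estimated correlation), and 0 members passed in limma over all genes or when adjusted over the list alone, with 6 lower at an unadjusted p under 0.05. This call was lost without Tg 1 (median -0.14, adjusted p = 0.23) and without wild type 3 (adjusted p = 0.11). Hsd17b7 had a log2 fold change of -0.87 ± 0.24 (SE; adjusted p = 0.094, limma). Oxidative phosphorylation genes had a median of -0.06 over 27 members, and 0 passed in limma over all genes or when adjusted over the list alone, with 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.30).

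Genes of the pre-TCR complex and its proximal signalling were higher as a list, with a median log2 fold change of 0.28 over 18 members, 17 of them positive (camera, adjusted p = 0.0016; adjusted p = 0.20 with an estimated correlation). Of these, 2 rose, and 3 rose when adjusted over the list alone. The CD3 chain genes Cd3g and Cd3d rose by 0.72 ± 0.12 and 0.58 ± 0.11 on the log2 scale, and Cd3e had a log2 fold change of 0.57 ± 0.14 (SE; adjusted p = 0.063, limma). In the list of p53 targets and apoptosis genes, 16 of 19 members were positive, with a median of 0.34 (camera, adjusted p = 0.012; adjusted p = 0.27 with an estimated correlation) and of 0.22 without wild type 1. Its members called in limma over all genes numbered 0, against 6 at an unadjusted p under 0.05 and 5 when adjusted over the list alone. These 5 were Bcl2l11 and Bbc3, which promote apoptosis, with log2 fold changes of 1.08 and 1.12, Mcl1 and Bcl2, which oppose it, with 0.84 and 0.82, and Pmaip1, which promotes it. Pmaip1 was not detected in wild-type cells and was at least 1.62-fold higher in Tg cells. Beside these 5, the p53 target genes Cdkn1a, Mdm2, Bax and Ccng1 had log2 fold changes of 0.34, -0.37, 0.03 and 0.08. They did not pass in limma over all genes or over the list alone. The list mixes p53 targets with other apoptosis genes, so it does not by itself show a rise of p53 targets.

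None of the 4 lists of thymocyte stages (0) passed camera, while single members did in limma. In the DN3 programme, 2 of 21 members rose over all genes and 3 when adjusted over the list alone (camera, adjusted p = 0.36; median 0.05). Il2ra, which encodes CD25, rose by 1.54 ± 0.23 and Dtx1 by 2.54 ± 0.39 on the log2 scale (SE), and Notch3 had a log2 fold change of 0.75 ± 0.20 (SE; adjusted p = 0.075, limma). Of 16 genes induced by beta-selection, Cd2 alone passed and fell by 1.55 ± 0.31 (SE), with a list median of -0.21 (camera, adjusted p = 0.090), and 3 were lower when adjusted over the list alone. With 1 array left out, the beta-selection median ran from -0.49 to -0.16. Among 11 markers of later thymocyte stages, Ly6c1 rose by 1.43 and Cd53 by 1.19, and Itm2a fell by 1.28 (camera, adjusted p = 0.25; median 0.15); adjusted over the list alone, 4 rose and 2 fell. Of 11 genes of early progenitor stages, Bcl11a fell by 1.47 and Gfi1b, not detected in Tg cells, was at least 1.67-fold lower (camera, adjusted p = 0.25, median -0.33), and 3 fell when adjusted over the list alone. Across the fits with 1 array left out, the early progenitor median ran from -0.51 to -0.085. The early progenitor list passed without wild type 1 (camera, adjusted p = 0.042), and the beta-selection list passed in 4 of 24 alternatives, among them without wild type 2 and without Tg 3 (camera, adjusted p = 0.033 and 0.042).

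In the list of calcium, calcineurin and NFAT genes, 3 of 27 members fell, Nfatc3, Camk4 and the calmodulin gene Calm3, which fell by 0.60 ± 0.12 on the log2 scale (SE). Of these, 2 are study targets. The median was -0.02 and the list did not pass (camera, adjusted p = 0.72); adjusted over the list alone, 3 fell and 1, Calm2, rose. Of 12 genes reported elsewhere as miR-185 targets, Igf1r, the receptor of insulin-like growth factors, was 3.73-fold lower, from a log2 intensity of 8.68 ± 0.07 to 6.78 ± 0.57 (SD, n = 3 each; adjusted p = 0.020, limma), and 11 did not pass, and the same 1 passed when adjusted over the list alone. The median of these reported miR-185 targets was -0.25, and the list did not pass camera (adjusted p = 0.11) but passed fry (adjusted p = 0.042), and camera with array weights. Tango2, the host gene of the mouse Mir185 locus, had a log2 fold change of 0.39 ± 0.23 (SE; adjusted p = 0.40, limma). Of 9 measured host and neighbouring genes, Ranbp1 fell by 0.59 ± 0.12 (SE) and Prodh had a log2 fold change of 0.63 ± 0.18 (SE; adjusted p = 0.091, limma). Adjusted over the list alone, 1 was higher and 1 lower, and as a list they did not pass (camera, adjusted p = 0.99; median 0.01, with the test pointing down). Among the rest, Dgcr8, Trmt2a, Zdhhc8, Txnrd2 and Gnb1l had log2 fold changes of 0.01, 0.11, 0.16, -0.40 and -0.15 and did not pass. The arrays do not measure mature miR-185.

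Of 21 endoplasmic reticulum chaperone and unfolded protein response genes, the pseudokinase gene Trib3 was not detected in wild-type cells and was at least 1.73-fold higher in Tg cells (adjusted p = 0.037, limma), and the list did not pass (camera, adjusted p = 0.99), with a median of -0.11, a mean of -0.01 and a test pointing up. Adjusted over the list alone, 1 rose and 1, Sdf2l1, fell. Of 16 immediate early and stress genes 0 passed in limma over all genes, with 2 at an unadjusted p under 0.05, and 1, Klf2, rose when adjusted over the list alone. The median was 0.62 (camera, adjusted p = 0.10), and the list passed in 8 of 24 alternatives, among them without Tg 1, without wild type 2 and without wild type 3 (camera, adjusted p = 0.0042, 0.037 and 0.023). Without wild type 1 and without Tg 3 the median of the immediate early and stress list was 0.35 and 0.26 (camera, adjusted p = 0.49 and 0.75).

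**Figure D3:**
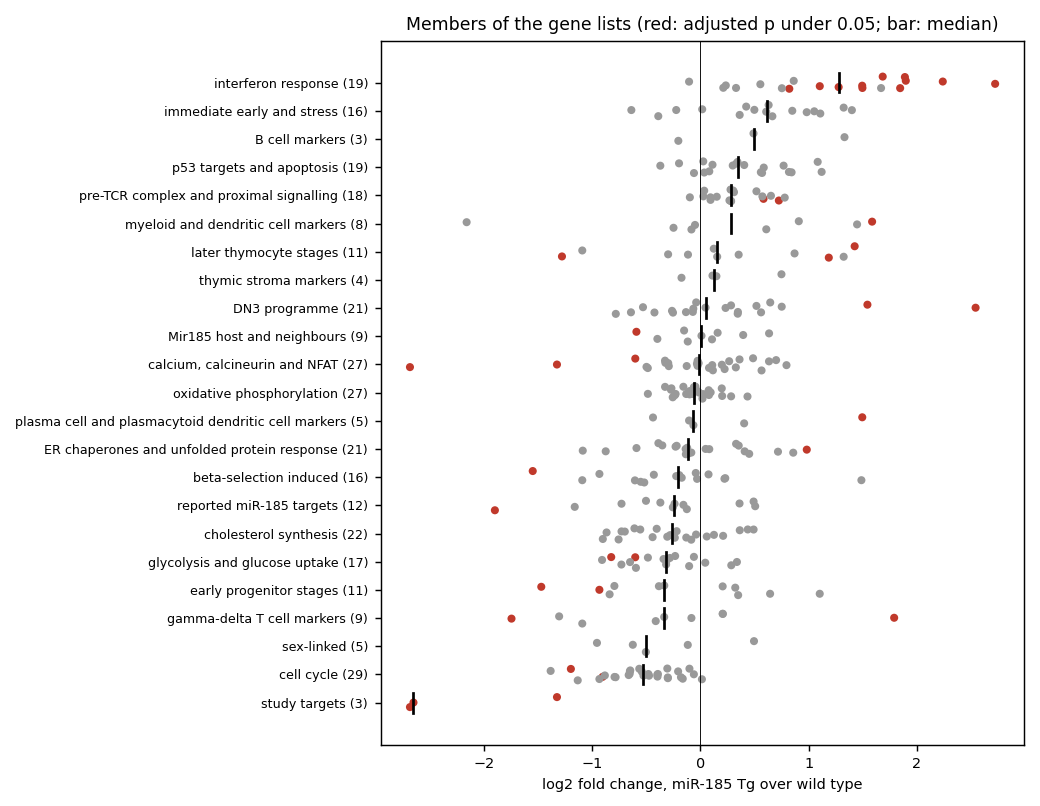
Log2 fold change of miR-185 Tg over wild type (horizontal axis) for each measured member of 23 gene lists (1 point per gene, number of members in brackets), with the list median as a vertical bar and genes with an adjusted p under 0.05 in red. The interferon list has a median of 1.28 and the cell cycle list a median of -0.53.

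Markers of other cell types were measured in the same way. Of 8 measured myeloid and dendritic markers, the lysozyme gene Lyz1 rose by 1.59 ± 0.28 on the log2 scale (SE), with a list median of 0.28 (camera, adjusted p = 0.30). Adjusted over the list alone, 4 rose, Lyz1, Lyz2, Cst3 and H2-Ab1, the last 3 with log2 fold changes of 1.45 ± 0.45, 0.61 ± 0.17 and 0.91 ± 0.32 (SE), and 1, S100a8, fell. Of 5 plasma cell and plasmacytoid dendritic cell markers, a group that shares Mzb1, Ly6d was 2.82-fold higher (adjusted p = 0.0062, limma), with a median of -0.07, a mean of 0.26 and a test pointing up (camera, adjusted p = 0.36), and the same 1 passed when adjusted over the list alone. Of 9 gamma-delta T cell markers, the kinase gene Blk rose by 1.79 ± 0.19 and Cd163l1 fell by 1.75 ± 0.37 (SE), with a median of -0.34 (camera, adjusted p = 0.36). Adjusted over the list alone, 1 rose and 3 fell, and with 1 array left out the median ran from -0.46 to -0.13. The natural killer cell gene Nkg7, 1 of 2 measured markers of that type, rose by 1.57 ± 0.22 (SE), also when adjusted over the list alone, and Prf1 had a log2 fold change of 0.21. For the 3 B cell markers 0 passed in limma, with 1 at an unadjusted p under 0.05, and 1, Cd74, not detected in wild-type cells and at least 2.05-fold higher in Tg cells, rose when adjusted over the list alone (camera, adjusted p = 0.36; median 0.49). For the 4 thymic stroma markers 0 passed in limma over all genes or when adjusted over the list alone, with 1 at an unadjusted p under 0.05 (camera, adjusted p = 0.36; median 0.13). Both measured erythroid markers, Hbb-b1 and Hba-a1, had log2 fold changes of -1.44 ± 1.16 and -1.72 ± 1.27 (SE; adjusted p = 0.55 and 0.51, limma), and 0 passed over all genes, when adjusted over the list alone or at an unadjusted p under 0.05. The same held for the 5 sex-linked genes, of which 0 passed in limma by any of these rules, with a median of -0.51 (camera, adjusted p = 0.52).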

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

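Alternatives that average or leave out both wild type 2 and 3, or add a covariate, were chosen after seeing the data. The number of changed genes depended on which arrays entered. Leaving out each array in turn gave 1 to 1708 changed genes, 1 to 930 higher and 0 to 778 lower, and 0 to 3 study targets. In limma, the fit without wild type 1 called 1 gene with 1774 at an unadjusted p under 0.05, and the fit without wild type 3 called 2 with 1516. Counts with 2 arrays in a group rest on fewer samples. With wild type 2 and 3 averaged as 1 sample, 36 genes changed, 23 higher and 13 lower, with 0 study targets called. Without both, 1 gene changed, 1 higher and 0 lower (704 at an unadjusted p under 0.05), with 0 study targets, and the lone wild-type array is assumed to vary like the Tg arrays. With Hbb-b1 as a covariate, 123 changed, 84 higher and 39 lower, with 1 study target. With Ddx3y as a covariate, 1944 changed, 1045 higher and 899 lower. Array weights, which gave Tg 2 a weight of 0.121 and wild type 3 of 5.37, gave 4472 calls, 2343 higher and 2129 lower. The authors' series values, unnormalized, gave 256, 157 higher and 99 lower. No filter, with 28888 genes tested, gave 312, 195 higher and 117 lower. Median scaling gave 380 calls, with 127 lower. An unadjusted p under 0.05 with a fold of at least 1.5 gave 1804, 1036 higher and 768 lower, and an adjusted p under 0.10 gave 1049, 605 higher and 444 lower. A plain two-sample test without moderation gave 81, 45 higher and 36 lower, with 2341 at an unadjusted p under 0.05. Apart from the replicate block, given below, the other alternatives gave 424 to 559 calls. Apart from fewer genes, samples or degrees of freedom where stated, the cause was not tested.

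Camera called 7 lists, and 0 with an estimated correlation, where 4 lists had an unadjusted p under 0.05, against 6 by fry. Apart from that setting, the interferon, cell cycle, pre-TCR, p53 and study target lists were called under every alternative in which they were tested. The study target list was chosen on these samples, so its calls are not independent evidence. The glycolysis call was lost by fry, and the cholesterol call under 8 alternatives, with adjusted p up to 0.42. Lists not called passed in 19 cases. The immediate early and stress list passed with the authors' series values, the replicate block (adjusted p = 0.015), the Hbb-b1 covariate, wild type 2 and 3 averaged or both left out, and 3 single arrays left out. The beta-selection list passed with the authors' series values, without both, and without 2 single arrays. The DN3 and oxidative phosphorylation lists passed without both, the later-stage and myeloid lists under the strict filter, the early progenitor list without 1 array, and the reported miR-185 targets by fry and with array weights. Of 16 lists not called, 11 had a median that crossed 0 somewhere (38 cases). Of 115 named genes, 50 were called. Over all alternatives 325 calls were lost and 114 gained. With all 6 arrays and no block or covariate, an alternative ended the calls of Calm3, Camk4, Cd3d, Cd3g, Cd53, Cdc6, H19, Itm2a, Ldha, Ly6c1, Nfatc3, Ranbp1, Tpi1 and Trib3. Of the uncalled genes, 16 of 65 crossed 0 (37 cases).

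With the replicate number of the titles as a block, 264 genes changed, 176 higher and 88 lower. Deviations of same-numbered arrays from their group means correlated at -0.25, 0.15 and -0.26, which gave no sign of pairing. Wild type 1 correlated best with Tg 3 (0.37), and wild type 2 and 3 with Tg 1 (0.20 and 0.19). Deviations within a group sum to 0 and wild type 2 and 3 lay close together. These correlations are thus not separate comparisons and cannot exclude pairing. The alternatives for the seed-site shift were not run.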

Other observations

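All tests here except that of genes that decline after birth were chosen after the result was seen. Of 12 genes of antigen presentation by MHC class I molecules that were picked after their values were seen, 11 rose in miR-185 Tg cells, and no test of them as a group was run. B2m, the light chain of class I molecules, rose by 0.93 ± 0.14, H2-K1 by 2.14 ± 0.24 and H2-D1 by 2.01 ± 0.24 on the log2 scale, and Nlrc5, a transactivator of class I genes, by 2.45 ± 0.29 (SE). Of 9 further genes not looked at before, 1, H2-M3, passed and rose by 1.49 ± 0.23 (SE), and 8 did not pass, with log2 fold changes down to 0.19 for Erap1 and 0.02 for Psme2. Tap1, a peptide transporter gene, had log2 intensities of 7.31 ± 0.26 in wild type and 8.81 ± 0.77 in Tg cells (SD, n = 3 each; adjusted p = 0.074, limma).

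Further changes were noted after their values were seen. Dtx4, a relative of Dtx1, rose by 2.08 ± 0.32 and Socs2, an inhibitor of cytokine signalling, by 2.40 ± 0.38 on the log2 scale (SE). Hoxa5 fell by 1.57 ± 0.21 (SE), beside the fall of Hoxa7. Igf2, H19 and Dlk1, imprinted genes abundant before birth, had log2 fold changes of -1.81 ± 0.35, -2.11 ± 0.47 and -1.41 ± 0.25 (SE), each called, with Igf2 detected on 2 and Dlk1 on 1 of the 3 Tg arrays.

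The count of 526 changed genes was set against the other ways to divide the arrays. There are 10 splits of 6 arrays into 3 and 3, too few for a share under 0.05. The real split gave 526 genes, as many as only 1 split did, and the highest other split gave 0 in limma. Each other split mixes wild-type and Tg arrays on both sides, so a group difference adds to its spread and lowers its count. Such a count is therefore not what would be found without a group difference. At an unadjusted p under 0.05 the real split gave 2487 genes and the highest other 795. The real split called 7 lists and the highest other 5. These 7 include the study target list, which was chosen on these samples and so favours the real split.

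The interferon response genes were higher in Tg cells, with a list median of 1.28. Contaminating myeloid, dendritic or plasmacytoid cells, which the gate on CD11b, CD11c and B220 would largely remove, bring their abundant transcripts. Of 7 tested lineage genes detected on all Tg arrays, 3 were higher at an unadjusted p under 0.05, Lyz1, Lyz2 and Cst3, with log2 fold changes of 1.59 ± 0.28, 1.45 ± 0.45 and 0.61 ± 0.17 (SE), and 4 were not (Irf8, Fcer1g, Lair1 and Tcf4). H2-Ab1, Ly6d and Bst2, markers of the lists above that were also detected on all Tg arrays, were left out of this count. H2-Ab1 and Ly6d were higher at an unadjusted p under 0.05 (limma), by 0.91 ± 0.32 on the log2 scale (SE) and 2.82-fold. Bst2 was not, with a log2 fold change of -0.11 ± 0.42 (SE). Of 25 lineage genes on the array, which also leave out these markers, 14 were detected on no Tg array, among them S100a8. These values point both ways, so such cells stay open as a source. A linked genome segment holding the MHC genes would not hold the list, since 10 of the 11 called members have no H2 gene among the 10 tested genes on either side, and with Hbb-b1 as a covariate for red blood cell RNA the list median was 1.35 and still past the camera threshold at the preset correlation. Without the covariate that call was lost with an estimated correlation (adjusted p = 0.20). For the 15 risen H2 genes such a segment stays open, and no genotype was analysed here. Of 76 other tested genes near them, 4 were called, or 5.26% against 4.23% of all tested genes. Psmb and Tap genes, predicted genes and clones were left out of the 76 but not out of all tested genes. An effect of the transgene on interferon signalling may explain the list, as may an infection or housing difference between the mice, which was not tested.

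Dtna went from undetected to a log2 intensity of 10.77. A single cross-reacting probe is argued against by 5 of 5 probes, each detected on every Tg array and on no wild-type array. A regional effect around Dtna, such as a transgene that inserted nearby, could not be decided: of the 20 nearest tested genes 1, Mocos, was called higher, by 0.80 ± 0.15 (SE), with a range from -0.79 to 1.17 over the 20. An effect of miR-185 itself on Dtna also stays open and was not tested.

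Igf2, H19 and Dlk1 were lower in Tg cells. Stromal cells in the wild-type samples stay open: Col1a1, Col3a1 and Sparc, 3 of 4 abundant stroma genes, were detected on no wild-type array, but Col1a2 was detected on 2 of them and on 0 Tg arrays. Younger wild-type mice could also give this pattern, and the labels give no ages. Igf2bp3, which also declines after birth and whose value had been seen, had a log2 fold change of -1.68 ± 0.41 (SE, adjusted p = 0.062, limma). Dntt, which rises after birth, had a log2 fold change of 0.29 ± 0.23 (SE, adjusted p = 0.55, limma). Of 16 other genes that decline after birth, not looked at before, 7 were measured, with a median log2 fold change of -0.0266 and values from -0.66 to 0.13. Of these, 4 were negative: Ezh2 (-0.66), Cdkn1c (-0.66), Igf2bp2 (-0.48) and Arid3a (-0.03). The 3 positive ones, Mdk, Meg3 and Grb10, were dim, with wild-type log2 intensities of 5.48, 5.22 and 4.73. For Grb10, near the lowest detected signals, little fall could show. The median of -0.0266 lies above the bound of -0.1 set beforehand for excluding age, but by less than the standard error of the members (0.13). Age therefore cannot be told apart from genotype here. The bound alone was met, and the requirement to pass it by more than the spread was applied after the value was seen.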
